A study of Caenorhabditis elegans with 3 samples.

How the data were processed

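PolyA RNA of young adult Caenorhabditis elegans of a fem-1 strain was measured by RNA sequencing in 3 samples, all labelled 2.5 days. The animals had been given RNAi by feeding, and the labels name 1 mock library, 1 dcr-1 RNAi library and 1 drsh-1 RNAi library. RNA was extracted with TRIzol and libraries were made with the TruSeq kit for the HiSeq2000, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.06, Cuffdiff 2.1.1, Cufflinks and SAMtools, without roles or order. The genome build and the gene annotation were not given in the sources used here, so no coordinates are reported.

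The authors deposited 2 tables, 1 per RNAi target. Each gives, per gene name, an FPKM value (fragments per kilobase of transcript, scaled to the number of mapped fragments) for mock, an FPKM value for the RNAi library and a log2 ratio. The deposited log2 ratio equals log2 of (RNAi FPKM + 1) over (mock FPKM + 1) to within 5.0e-12. The tables have no header. The RNAi library of each table was taken from the table's name, and mock was taken as the column whose values both tables share and which is the denominator of the deposited log2 ratio. How the authors scaled the FPKM values between libraries was not given in the sources used here.

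For dcr-1 RNAi 9631 genes are listed and for drsh-1 RNAi 9996 genes, with 9459 in both tables. Every listed gene is above 2 FPKM in both libraries of its table, the lowest value being 2.00 FPKM. A gene under that level in either library is therefore missing, and genes switched on or off between libraries are undercounted. The mock value was equal in both tables (difference at most 1e-09) for 9043 shared genes and unequal for 416. Of the unequal genes, 411 differed by at least 2 FPKM and 375 had the lower mock value in the dcr-1 table. Several transcripts are annotated for 93.1% of the unequal genes matched to the annotation and for 36.7% of the equal ones. For such a gene the listed FPKM may not cover the same transcripts in both tables. The 2 RNAi libraries were therefore compared directly only over the 9043 genes with equal mock values.

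Read counts and library sizes were not analysed here, so the depth of each library is unknown and no interval or detection limit from counting error is given. Each group had 1 library. No difference between groups has a replicate check, and no p-value or standard deviation between samples could be computed.

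From the deposited FPKM values, log2 ratios of (FPKM + 1) were computed for 3 comparisons: dcr-1 RNAi against mock, drsh-1 RNAi against mock, and dcr-1 RNAi against drsh-1 RNAi. The pseudocount of 1 FPKM understates the ratio of genes with low values. A filter of a mean of at least 1 FPKM removed 0 genes, since the tables had been filtered more strictly. Genes at least 2-fold apart were counted as a description of size, not as a test.

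Gene lists were fixed before the data were examined: small RNA pathway factors, heterochronic and known microRNA target genes, microRNA genes, reported ERGO-1 class siRNA target transcripts, the intracellular pathogen response, antibacterial and antifungal response effectors, C-type lectins, heat shock and cytosolic chaperone genes, endoplasmic reticulum and mitochondrial stress genes, xenobiotic metabolism (cytochrome P450, UGT and GST families), cuticle collagens, molting cycle genes, yolk proteins, oocyte and eggshell genes, germ line stem cell, P granule and meiosis genes, sperm genes, early zygotic embryonic genes, body wall and pharyngeal muscle genes, neuronal genes, intestinal proteases, fatty acid and lipid metabolism, DAF-16 pathway and longevity genes, cytosolic ribosomal proteins, proteasome subunits, histones, mitochondrially encoded genes, nuclear-encoded oxidative phosphorylation subunits, F-box, MATH and BATH domain families, and nuclear hormone receptors. A list with at least 5 listed genes was placed by the percentile of its median log2 ratio among 10000 random lists of the same size, matched on mean expression in 20 bins. A list under the 2.5th or over the 97.5th percentile is said to stand apart, which chance alone would give for 5% of lists of independent genes. The numbers of lists expected by chance given below assume such genes. The percentile describes these libraries and is no test of the conditions, and genes of a list are not independent. Families of near-identical genes (yolk proteins, collagens, major sperm proteins, histones, F-box genes) can share reads, so values of single members are uncertain.

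Named genes were chosen by a rule fixed in advance. It takes dcr-1, drsh-1 and pash-1, the 10 highest and 10 lowest log2 ratios of each comparison against mock and the 5 highest and 5 lowest of the direct comparison among genes with a mean of at least 5 FPKM, the 3 farthest members of each list that stood apart, only on the side to which it stood apart, under the same minimum, and lin-14, lin-28, lin-41, hbl-1, lin-29, col-19, vit-2, alg-1, alg-2 and rncs-1. Genes behind some counts of 5 or fewer, and genes of families searched later, are also named, and those were chosen after their values were seen.

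Both comparisons against mock share the mock library. Their correlation and overlap across genes were set beside 100 simulations of unchanged libraries against a shared control, with the spread taken from drsh-1 RNAi against mock, and beside the overlap of independent lists. The placing of lists was tested on simulated data, by adding a known shift to random lists of the real genes after shuffling. In dcr-1 RNAi against mock (9631 genes), a shift of 0.5 on the log2 scale put 95% of lists of 15 genes and 99% of lists of 30 genes over the 97.5th percentile, and a shift of 0.25 did so for 47% and 75%. In drsh-1 RNAi against mock (9996 genes), a shift of 0.25 did so for 91% of lists of 15 genes. In all 3 comparisons, lists without a shift crossed the upper limit in at most 6% of runs and the lower limit in at most 4%. These were random genes with shuffled ratios, so the rates do not cover lists whose genes vary together.

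Gene names were matched to Ensembl release 115 (WBcel235) for 96.1% of the genes of the dcr-1 table and 95.9% of those of the drsh-1 table. The annotation was used for 3' UTR lengths and transcript numbers only. The alternatives were pseudocounts of 0.1 and 5 FPKM, no filter, a minimum mean of 5 FPKM, centring on the median ratio, a common upper quartile, the authors' deposited log2 ratio, thresholds of 1.5-fold and 4-fold, the mean of a list in place of its median, and unmatched random lists. After the data were examined, leaving out or keeping the genes with unequal mock values and random lists matched also on 3' UTR length (10 expression bins and 5 length bins) were added. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.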

Results

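The series compared knockdown of Dicer (dcr-1), the RNase III enzyme that cuts double-stranded RNA and microRNA precursors into small RNAs, with knockdown of Drosha (drsh-1), the nuclear RNase III enzyme that releases microRNA precursors, and with a mock control. The dcr-1 library was compared with mock to assess the effect of Dicer on polyA RNA levels, and drsh-1 RNAi and mock served as controls. The fem-1 strain was used because loss of dcr-1 makes animals sterile, so that sterile animals were compared with each other, per the labels. There was 1 library per group, so none of the differences has a replicate check. The depth of the libraries is unknown. The FPKM values of the listed genes summed to 668652 in mock and 819608 in dcr-1 RNAi over the dcr-1 table, and to 674897 in mock and 709653 in drsh-1 RNAi over the drsh-1 table.

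Each targeted gene was lower in its own RNAi library than in mock. The dcr-1 transcript was at 36.8 FPKM in mock, 23.8 FPKM in dcr-1 RNAi (log2 ratio -0.61) and 33.2 FPKM in drsh-1 RNAi (-0.14). The drsh-1 transcript was at 31.999 FPKM in mock and 20.9 FPKM in drsh-1 RNAi (-0.59). In the dcr-1 table it was at 26.2 FPKM in mock and 33.2 FPKM in dcr-1 RNAi (0.33), and its mock value is thus 1 of those that differ between the tables. pash-1, which encodes the RNA-binding partner of Drosha, had log2 ratios of -0.11 in dcr-1 RNAi and 0.27 in drsh-1 RNAi. On the (FPKM + 1) scale the level left in its own RNAi library was 0.657 of mock for dcr-1 and 0.665 for drsh-1. Falls of at least 1.5-fold from mock were found for 1336 of 9631 genes in dcr-1 RNAi and 519 of 9996 in drsh-1 RNAi. A fall of this size was thus not particular to the targeted genes.

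In dcr-1 RNAi against mock, the medians of cuticle collagens and muscle genes were above mock, and that of DAF-16 pathway and longevity genes below it. Of 5 yolk genes, 3 were above mock and 2 below. The cuticle collagen col-93 was at 18.04 FPKM in mock and 2043 FPKM in dcr-1 RNAi (log2 ratio 6.75), col-160 at 48.9 and 1059 FPKM (4.41), and col-159 at 2.54 and 70.9 FPKM (4.34). acdh-1, an acyl-CoA dehydrogenase of propionate breakdown, was at 47.2 FPKM in mock and 703 FPKM in dcr-1 RNAi (3.87), and ife-1, a cap-binding translation factor of the eIF4E family, at 11.8 and 203 FPKM (3.99). The other genes among the 10 highest were F46F2.3 (6.27), F53F1.4 (5.09), Y69H2.14 (4.59), C32H11.4 (4.39) and F43E2.5 (3.86). Among the 10 lowest, sodh-1, an alcohol dehydrogenase, was at 661 FPKM in mock and 26.99 FPKM in dcr-1 RNAi (-4.56), the small heat shock gene hsp-12.3 at 364 and 20.4 FPKM (-4.09), the metallothionein gene mtl-1 at 703 and 43.2 FPKM (-3.99), and acs-2, an acyl-CoA synthetase of fatty acid oxidation, at 169 and 10.9 FPKM (-3.84). The aldehyde dehydrogenase gene alh-1 (-3.87), the yolk gene vit-6 (-4.26), F46B6.8 (-4.90), C06G3.3 (-4.05), C54F6.5 (-3.73) and F58D5.5 (-3.73) made up the rest. In total 646 genes were at least 2-fold higher and 629 at least 2-fold lower than mock, 13.2% of 9631. Which side held more genes depended on the scaling, with 554 higher and 695 lower after centring on the median ratio and 545 and 702 with a common upper quartile. The 2 FPKM limit bears on it too. For drsh-1 RNAi only, 537 genes were listed, 55 of them at 10 FPKM or more in mock, and for dcr-1 RNAi only, 172 genes. Genes under 2 FPKM in dcr-1 RNAi would be among the 537, so the count of lower genes may be too small.

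Of 28 lists with enough genes, 13 stood apart from random lists in dcr-1 RNAi against mock, where 1.40 were expected by chance, 9 of them high and 4 low. Cuticle collagens had a median log2 ratio of 1.75 (100th percentile of random lists), with 29 of 47 genes at least 2-fold higher and only col-116 (-1.07) at least 2-fold lower. col-19, an adult-specific collagen regulated by the heterochronic pathway, was at 340 FPKM in mock and 1455 FPKM in dcr-1 RNAi (2.095). Body wall and pharyngeal muscle genes had a median of 0.56 (100th percentile), and 10 of 31 were at least 2-fold higher. They included the troponin T genes mup-2 (2.22) and tnt-2 (1.77) and the muscle gene dim-1 (1.97), whose mock value differs between the tables. The 5 listed yolk genes were split, with 3 at least 2-fold higher and 2 at least 2-fold lower, and their median of 2.64 (100th percentile) stands beside a mean of 0.58 (77.8th percentile). vit-1 (3.75), vit-4 (3.74) and vit-3 (2.64) were higher, whereas vit-2 was at 1165 FPKM in mock and 147 FPKM in dcr-1 RNAi (-2.98) and vit-6 at 62.2 and 2.29 FPKM. Reads can be shared between the near-identical yolk genes.

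Cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation subunits and 4 other lists were also high, with smaller medians than the collagens. Cytosolic ribosomal proteins had a median log2 ratio of 0.60 (100th percentile, matched random lists 0.20 to 0.42), and 73 of 75 were above mock, led by rpl-34 (1.22), rpl-18 (1.19) and rps-5 (1.18). Their mean was at the 97.4th percentile, just inside the range of random lists. Nuclear-encoded oxidative phosphorylation subunits had a median of 0.46 (99.8th percentile, matched random lists 0.01 to 0.36), with 30 of 31 above mock, among them the ATP synthase genes atp-5 (2.73), atp-2 (1.68) and asb-1 (1.01). Such counts were not particular to these lists, since 30 of 31 proteasome subunits were also above mock and that list did not stand apart (96.1st percentile). The xenobiotic metabolism families had a median of 0.25 (100th percentile), and 17 of 86 were at least 2-fold higher against 4 lower, cyp-34A9 (-2.59), cyp-32B1 (-2.08), gst-15 (-2.03) and cyp-33E1 (-1.50). ugt-41 (2.79), ugt-22 (2.71) and cyp-35C1 (2.29) were the highest of these families. Another 9 of their genes were listed for drsh-1 RNAi only and 1 for dcr-1 RNAi only, so falls under 2 FPKM may be left out. Antibacterial and antifungal effectors had a median of 0.30 (99.8th percentile, 96.03rd for the mean), with 18 of 60 at least 2-fold higher and 10 at least 2-fold lower. F08G5.6 (2.499), nlp-34 (2.49) and cnc-7 (2.37), the last 2 encoding antimicrobial peptides, were the highest. Lipid metabolism genes had a median of 0.26 (98.2nd percentile) with members on both sides, 8 of 45 at least 2-fold higher, such as the enoyl-CoA hydratase gene ech-6 (1.62) and the fatty acid elongase gene elo-2 (1.52), and 6 lower. That list no longer stood apart among genes of at least 5 FPKM or by its mean, whose percentile was the lowest at 63.4. Sperm genes had a median of 0.53 (99.7th percentile) from 11 genes, 5 of them with a mean of at least 5 FPKM, such as msp-81 at 3.11 and 8.03 FPKM (1.13), spe-15 (0.73) and spe-6 (0.30). They did not stand apart by the mean or among genes of at least 5 FPKM, with a lowest percentile of 83.8.

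Below mock in dcr-1 RNAi stood the DAF-16 pathway and longevity genes, with a median of -0.28 (0.02nd percentile). Of 23 genes, 13 were below mock and 10 above. At least 2-fold lower were 10, and 2 were at least 2-fold higher, dod-24 (1.52) and the metallothionein gene mtl-2 (1.25). Besides mtl-1 the lowest were far-7 (-2.66), encoding a fatty acid and retinol binding protein, and the transhydrogenase gene nnt-1 (-2.54). Heterochronic and known microRNA target genes had a median of -0.63 (1.11th percentile), with 7 of 8 below mock. kin-20, a casein kinase gene, was at 25.9 FPKM in mock and 7.43 FPKM in dcr-1 RNAi (-1.68), lin-41, a let-7 target encoding a TRIM protein, at 35.96 and 12.7 FPKM (-1.43), and let-60, the worm Ras gene, at 84.1 and 33.8 FPKM (-1.29). The mock values of kin-20 and lin-41 differ between the tables, and lin-28, an RNA-binding heterochronic regulator, had -0.53. lin-14 was listed only in the drsh-1 table, and hbl-1 and lin-29 were in neither. Of this list, 5 genes, lin-14 included, were listed for drsh-1 RNAi only, against 1 for dcr-1 RNAi only. Falls under 2 FPKM may thus be left out of its median and of its count of genes below mock. Across the 8980 genes with an annotated 3' UTR, the log2 ratio had a rank correlation of -0.29 with 3' UTR length, genes not being independent replicates. The heterochronic list did not stand apart when random lists were matched on 3' UTR length or when genes with unequal mock values were left out, its highest percentile being 5.78. Oocyte and eggshell genes had a median of -0.01, under the 0.05 to 0.37 that held 95% of matched random lists (0.46th percentile), with 0 of 38 at least 2-fold higher and 3 lower. Those 3 were the RNA-binding protein gene spn-4 (-2.22), the cyclin B gene cyb-1 (-2.059) and lin-41. This list was inside the range of random lists when these were unmatched or also matched on 3' UTR length, with a highest percentile of 23.03. F-box, MATH and BATH domain genes had a median of -0.09 (0.96th percentile), with 11 of 165 at least 2-fold lower and 4 higher, and math-27 (-1.96, with unequal mock values), fbxa-1 (-1.50) and bath-10 (-1.49) the lowest. Another 24 of them were listed for drsh-1 RNAi only, against 3 for dcr-1 RNAi only, so falls under 2 FPKM may be left out.

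The other 15 lists did not stand apart in dcr-1 RNAi against mock. Small RNA pathway factors had a median log2 ratio of 0.01 over 38 genes, with 0 at least 2-fold higher and 2 lower, the microRNA cofactor gene nhl-2 (-2.55) and the RNA-editing gene adr-1 (-1.71). Within the list, the Argonaute genes of the microRNA pathway alg-1 and alg-2 had 0.23 and -0.32. The noncoding RNA rncs-1, reported to inhibit Dicer, was at 30.8 FPKM in mock, 19.1 FPKM in dcr-1 RNAi (-0.66) and 18.8 FPKM in drsh-1 RNAi (-0.68). Medians were 0.06 for reported ERGO-1 class siRNA targets, 0.37 for the intracellular pathogen response, 0.11 for C-type lectins, 0.03 for heat shock and chaperone genes, 0.20 for endoplasmic reticulum and mitochondrial stress genes, and -0.02 for molting cycle genes. They were -0.00 for germ line stem cell, P granule and meiosis genes, 0.10 for early zygotic genes, -0.02 for neuronal genes, 0.39 for intestinal proteases, 0.40 for proteasome subunits, -0.01 for histones, 0.03 for mitochondrially encoded genes and -0.00 for nuclear hormone receptors. Falls under 2 FPKM may be left out of these medians. Of C-type lectins, 11 were listed for drsh-1 RNAi only and 1 for dcr-1 RNAi only, and of nuclear hormone receptors 17 and 4. No microRNA gene was listed in either table, 0 in each.

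**Figure D1:**
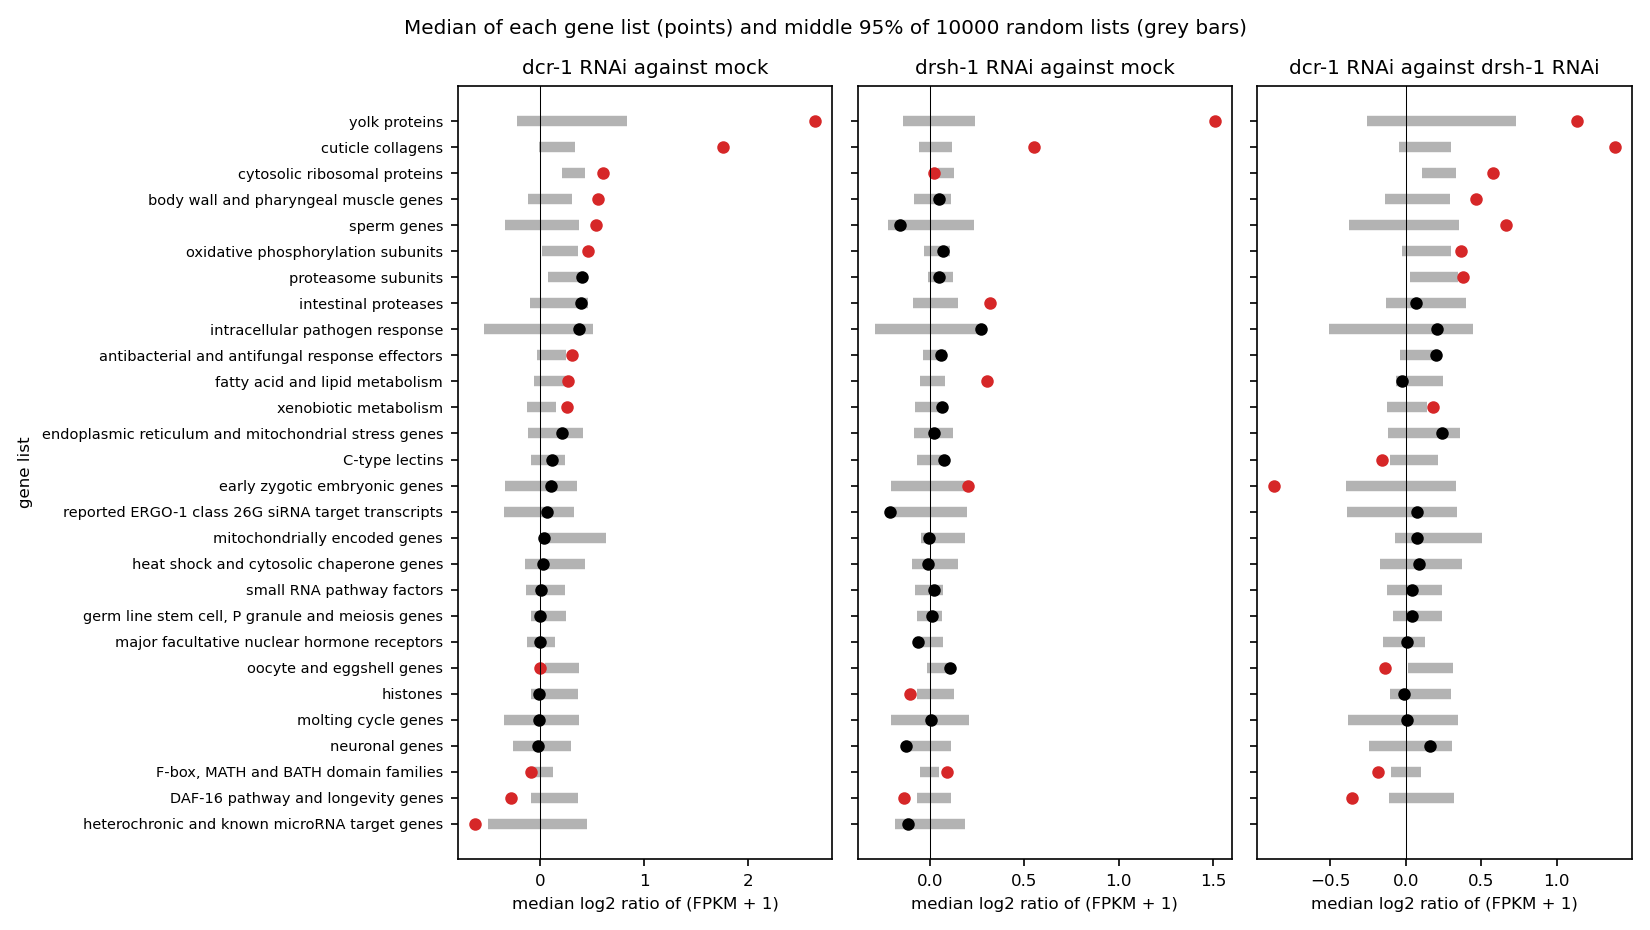
Median log2 ratio of (FPKM + 1) of each gene list (points, x axis) in the 3 comparisons, 1 panel each with its own x scale, beside the middle 95% of 10000 random lists matched on expression (grey bars). Red points lie outside the range of random lists, 13 of 28 lists for dcr-1 RNAi against mock, 9 of 28 for drsh-1 RNAi against mock and 13 of 27 for dcr-1 RNAi against drsh-1 RNAi.

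In drsh-1 RNAi against mock, fewer genes were apart, 191 at least 2-fold higher and 159 at least 2-fold lower of 9996 (3.50%), and the standard deviation of the log2 ratio across genes was 0.41 against 0.73 in dcr-1 RNAi. Collagens and yolk genes were above mock, and histones and DAF-16 pathway and longevity genes below it. K06G5.1 was at 5.15 FPKM in mock and 69.0 FPKM in drsh-1 RNAi (log2 ratio 3.51), acdh-1 at 47.2 and 319 FPKM (2.73), col-93 at 18.04 and 147 FPKM (2.96), and atp-5 at 6.14 and 36.2 FPKM (2.38). F46F2.3 (3.11), Y5H2B.3 (2.57), B0024.4 (2.48), R10D12.9 (2.36), F58G6.3 (2.32) and ZK6.11 (2.30) completed the 10 highest. The lowest was cyn-4, a cyclophilin gene, at 53.3 FPKM in mock and 2.08 FPKM in drsh-1 RNAi (-4.14), near the limit of the table. It was followed by vha-12, a vacuolar ATPase subunit gene, at 43.99 and 2.71 FPKM (-3.60), the homeobox genes ceh-5 (-3.02) and tab-1 (-2.60), the collagen gene dpy-14 (-2.89), the bZIP transcription factor gene ces-2 (-2.87) and the insulin-like peptide gene ins-2 (-2.55). K06A1.3 (-3.01), F47G4.6 (-2.81) and W02D7.11 (-2.81) were also among the 10 lowest.

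Of 28 lists, 9 stood apart in drsh-1 RNAi against mock, 6 high and 3 low, where 1.40 were expected by chance. Cuticle collagens had a median of 0.55 (100th percentile), with 10 of 41 at least 2-fold higher, such as col-160 (1.88) and col-80 (1.62), and 2 at least 2-fold lower, dpy-14 and sqt-3 (-2.25). Another 6 collagens were listed for dcr-1 RNAi only, as genes under 2 FPKM in drsh-1 RNAi would be. The median and the count of lower collagens leave these out. col-19 was at 376 FPKM against 340 FPKM in mock (0.15). All 5 listed yolk genes were above mock, 3 of them at least 2-fold, with a median of 1.51 (100th percentile). vit-4 (2.08), vit-1 (1.68) and vit-3 (1.51) were the highest and vit-2 had 0.10. Lipid metabolism genes had a median of 0.30 (100th percentile), with 34 of 45 above mock, among them the desaturase gene fat-5 (0.85) and the lipid-binding protein gene lbp-6 (0.76). Intestinal proteases had a median of 0.32 (99.99th percentile, 94.98th for the mean), with 14 of 19 above mock, led by the cathepsin L gene cpl-1 (0.66), pcp-2 (0.65) and F28A12.4 (0.62). F-box, MATH and BATH domain genes had a median of 0.09 (99.98th percentile), with 20 of 186 at least 2-fold higher and 5 lower. bath-31 (1.94), fbxb-103 (1.88) and fbxb-92 (1.63) were the highest, and the list was at the 93.5th percentile among genes of at least 5 FPKM.

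Early zygotic genes, which are transcribed in the early embryo, were higher in 6 of 15 cases by at least 2-fold and lower in 0. vet-6 was at 4.60 FPKM in mock and 24.96 FPKM in drsh-1 RNAi (2.21), the T-box gene tbx-38 at 2.38 and 14.4 FPKM (2.19), and pes-10 at 2.96 and 14.3 FPKM (1.95). Their median of 0.20 was at the 97.51st percentile, at the limit, and fell within the range of random lists with a pseudocount of 0.1 or 5 FPKM (lowest percentile 95.7). The mean of 0.63 was at the 100th percentile. A separate list of embryonic epidermis, junction and morphogenesis genes, chosen after the lowest genes of this comparison were seen, had a median of -0.16 (0.11th percentile), with 28 of 40 genes below mock.

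The DAF-16 pathway and longevity genes had a median of -0.13 in drsh-1 RNAi (0.07th percentile), with 16 of 26 below mock, 10 above and 3 at least 2-fold lower. These 3 were hsp-12.6 (-1.57), mtl-1 (-1.44, at 703 FPKM in mock and 259 FPKM) and far-7 (-1.43). Histones had a median of -0.11 (0.47th percentile), with 4 of 26 at least 2-fold lower, the linker histone genes hil-7 (-1.65), his-24 (-1.27) and hil-3 (-1.09) and the core histone gene his-60 (-1.35). Of these, his-24 (-1.83), hil-3 (-1.20) and his-60 (-0.40) were also below mock in dcr-1 RNAi, where the list did not stand apart. Polyadenylated RNA covers most replication-dependent histone transcripts poorly, and copies of core histone genes are near-identical. In drsh-1 RNAi, cytosolic ribosomal proteins had a median of 0.02 and a mean of -0.02, under the 0.04 to 0.13 of matched random lists (0.30th percentile), with 0 of 74 at least 2-fold apart. rpl-25.1 (-0.65), rpl-26 (-0.47) and rpl-24.2 (-0.42) were the lowest, and the list did not stand apart with unmatched lists or lists matched on 3' UTR length, with a highest percentile of 74.5.

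The other 19 lists did not stand apart in drsh-1 RNAi against mock. Small RNA pathway factors had a median of 0.02 with 0 of 39 at least 2-fold apart, alg-1 (-0.30) and alg-2 (0.33) included. Heterochronic and known microRNA target genes had a median of -0.11 with 0 of 12 at least 2-fold apart. lin-14 was at 4.502 FPKM in mock and 2.057 FPKM in drsh-1 RNAi (-0.85), lin-28 had -0.32 and lin-41 -0.14. The intracellular pathogen response (0.27, 97.4th percentile), the xenobiotic families (0.07, 97.2nd percentile) and reported ERGO-1 class siRNA targets (-0.21, 2.57th percentile) came close to the limits. Medians were 0.06 for antibacterial and antifungal effectors, 0.08 for C-type lectins, -0.01 for heat shock and chaperone genes, 0.03 for endoplasmic reticulum and mitochondrial stress genes, 0.01 for molting cycle genes (with noah-1, noah-2 and wrt-10 at -1.86, -1.93 and -2.21), 0.11 for oocyte and eggshell genes and 0.01 for germ line genes. They were -0.16 for sperm genes, 0.05 for muscle genes, -0.13 for neuronal genes, 0.05 for proteasome subunits, -0.00 for mitochondrially encoded genes, 0.07 for oxidative phosphorylation subunits and -0.06 for nuclear hormone receptors.

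The direct comparison of both knockdowns, whose ratio does not use the mock values, covered the 9043 genes with equal mock values in both tables. Collagens, muscle genes and cytosolic ribosomal proteins were higher in dcr-1 RNAi than in drsh-1 RNAi, and DAF-16 pathway, early zygotic, oocyte and F-box genes lower. In total 388 genes were at least 2-fold higher and 523 at least 2-fold lower in dcr-1 RNAi, 10.1% of the genes compared. Genes listed for 1 knockdown only, 537 for drsh-1 RNAi and 172 for dcr-1 RNAi, are not in these counts. The highest were cyn-4 at 83.9 FPKM in dcr-1 RNAi and 2.08 FPKM in drsh-1 RNAi (log2 ratio 4.78), Y69H2.14 (4.48), ife-1 (4.107), F53F1.4 (4.08) and C32H11.4 (3.88). The lowest were vit-6 at 2.29 and 71.2 FPKM (-4.45), F58D5.5 (-3.74), F46B6.8 (-3.44), acs-2 (-3.43) and ZK858.1 (-3.34).

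Of 27 lists, 13 stood apart in the direct comparison, 8 high and 5 low, where 1.35 were expected by chance. Cuticle collagens had a median of 1.39 (100th percentile), with 27 of 41 at least 2-fold higher in dcr-1 RNAi and 0 lower. col-93 (3.79), col-159 (3.12) and dpy-14 (2.90) were the highest and col-19 had 1.95. Muscle genes had a median of 0.46 (99.9th percentile), led by the troponin genes tni-3 (2.29), mup-2 (2.01) and tni-1 (1.56). Ribosomal proteins (median 0.58, matched random lists 0.11 to 0.33, 73 of 74 above 0), oxidative phosphorylation subunits (0.37) and proteasome subunits (0.38) were higher too, with rpl-18 (1.45), rpl-4 (1.35), atp-2 (1.29), sdha-1 (0.91), rpn-5 (1.21) and rpt-4 (0.89) among the highest. The proteasome list was at the 94.9th percentile by its mean. Sperm genes had a median of 0.67 from 10 genes, and the named ones were at low levels. They were msp-81 at 8.03 and 3.29 FPKM (1.07), spe-6 at 8.65 and 4.48 FPKM (0.82) and spe-15 at 7.96 and 4.72 FPKM (0.65). The xenobiotic families had a median of 0.18, with gst-26 (2.18) and gst-24 (1.88) the highest, and were at the 89.6th percentile when random lists were matched on 3' UTR length. Yolk genes were again split, vit-1 (2.064), vit-4 (1.66) and vit-3 (1.13) being higher and vit-2 (-3.08) and vit-6 lower, so that the median of 1.13 and the mean of -0.54 differ in sign.

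Lower in dcr-1 RNAi than in drsh-1 RNAi were the early zygotic genes, with a median of -0.87 (0th percentile) and 6 of 13 at least 2-fold lower, such as tbx-38 (-2.01), sdz-28 (-1.70) and vet-6 (-1.43). The DAF-16 pathway and longevity genes had a median of -0.35 (0th percentile), with mtl-1 (-2.56), the ferritin gene ftn-1 (-1.84) and nnt-1 (-1.79) the lowest. Oocyte and eggshell genes had a median of -0.13 (0.01st percentile), and 3 of 36 were at least 2-fold lower, spn-4 (-2.74), cyb-1 (-2.16) and the germ granule gene meg-2 (-1.04). F-box, MATH and BATH domain genes had a median of -0.18 (0.01st percentile), with 27 of 161 at least 2-fold lower and 3 higher, fbxb-90 (-2.05), fbxb-33 (-1.90) and fbxb-103 (-1.76) being the lowest. C-type lectins had a median of -0.16 (0.58th percentile) and a mean of 0.02 (43.6th percentile), with clec-4 (-1.74), clec-84 (-1.12) and clec-66 (-1.09) the lowest. The other 14 lists had medians between -0.03 and 0.24 and percentiles between 6.53 and 94.8. The heterochronic list, with 4 genes left, was not placed. Among its members lin-28 had -0.21, and dcr-1 itself had -0.46 and pash-1 -0.38.

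**Figure D2:**
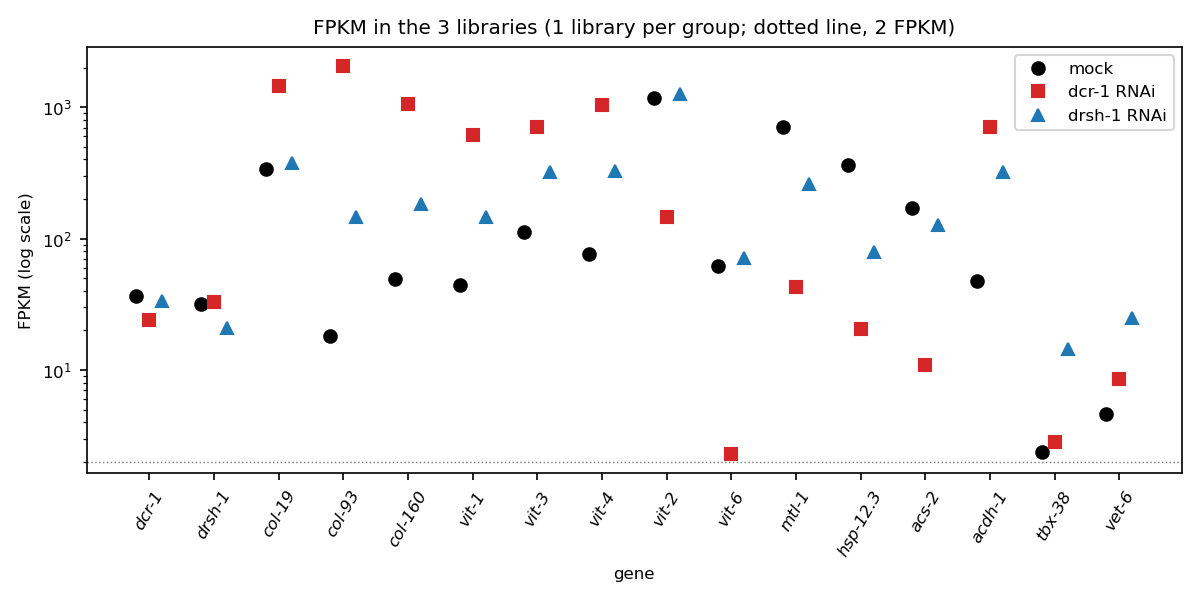
FPKM (y axis, log scale) of 16 named genes in mock (circles), dcr-1 RNAi (squares) and drsh-1 RNAi (triangles), 1 library each, with the 2 FPKM limit of the tables as a dotted line. The mock value of drsh-1 is that of the drsh-1 table, and col-93 spans 18.04 FPKM in mock to 2043 FPKM in dcr-1 RNAi.

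The log2 ratios of both knockdowns against mock were positively correlated across genes, where a shared mock library alone also gives a positive correlation. Over the 9043 genes, which are not independent replicates, Pearson's r was 0.49 and Spearman's rho 0.43, where 100 simulations of unchanged libraries against a shared control gave a mean r of 0.50 and a mean rho of 0.46. These are no like comparison, since the simulations gave both libraries the spread of drsh-1 RNAi against mock (variance of the dcr-1 ratio 0.537 observed and 0.169 simulated). The same limit holds for the share of genes with the same sign, 62.7% observed and 65.0% to 67.7% in the simulations. The covariance was 0.147, above all simulations (mean 0.0851, 0.0748 to 0.0930), which split the drsh-1 spread evenly between the mock and RNAi libraries, and a noisier mock library would raise it too. In both RNAi libraries 86 genes were at least 2-fold higher than mock, including col-93, F46F2.3, acdh-1, atp-5, vit-1, vit-3 and vit-4. The simulations gave 52.5 genes on average (32 to 67), and independent lists would give 12.1. Another 78 genes were at least 2-fold lower in both, including hsp-12.3, mtl-1, far-7, vha-12, tab-1 and W02D7.11, which lay inside the range of the simulations (mean 61.9, 46 to 83), with 8.56 for independent lists. The simulated libraries had on average 164 genes at least 2-fold higher and 166 lower in the place of dcr-1 RNAi, against 599 and 600 observed. In opposite directions 3 genes were at least 2-fold apart, ufd-1 and Y38E10A.13 (higher in dcr-1 RNAi and lower in drsh-1 RNAi) and F44G3.2 (the reverse). The simulations leave out real effects and the independent lists leave out the shared control, and with 1 mock library the control could not be split, so part of any excess over independent lists may come from the shared mock library.

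**Figure D3:**
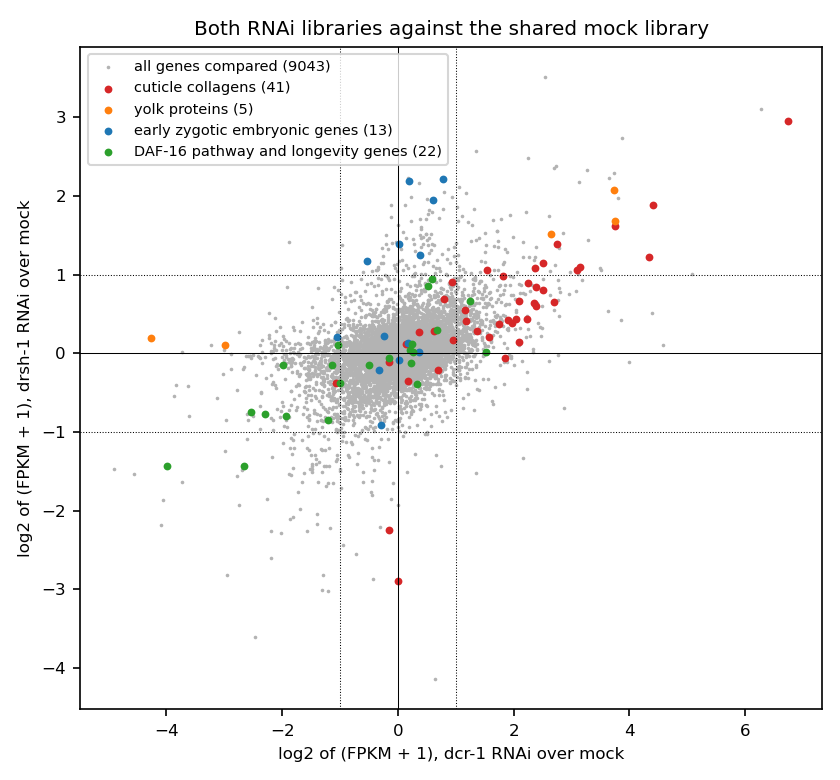
Log2 ratio of (FPKM + 1) of dcr-1 RNAi over mock (x axis) and of drsh-1 RNAi over mock (y axis) for 9043 genes (grey points), with collagens, yolk, early zygotic and DAF-16 pathway genes in colour and dotted lines at 2-fold. In total 86 genes lie past 2-fold at the upper right and 78 at the lower left, with the same mock library in both axes.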

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

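Leaving out or keeping genes with unequal mock values and matching random lists on 3' UTR length were chosen after the data were seen, and the other alternatives before. The log2 ratios of dcr-1 and drsh-1 in their own RNAi libraries and the correlation of both comparisons against mock kept their direction and size under every alternative run on them. No filter and the authors' deposited log2 ratio moved nothing, since the filter removes 0 genes and the deposited ratio is the one computed here, so these are no tests of stability. Centring on the median and a common upper quartile shift the ratios of all genes nearly alike, so they are no test of the list percentiles either. They did move the balance of higher and lower genes, to 554 and 695 or 545 and 702 in dcr-1 RNAi against mock and to 330 and 583 or 328 and 577 in the direct comparison. The total counts moved by over 1.5 times only with a pseudocount of 5 FPKM and with the threshold. With a pseudocount of 5 FPKM, 409 genes were at least 2-fold higher and 407 lower in dcr-1 RNAi against mock, 99 and 89 in drsh-1 RNAi against mock, 250 and 316 in the direct comparison, and 41 higher and 50 lower in both RNAi libraries. At 1.5-fold the counts were 1542 and 1336, 545 and 519, and 1216 and 1152 for the 3 comparisons, and at 4-fold 108 and 100, 20 and 24, and 53 and 73. With list means in place of medians, 8 lists stood apart in dcr-1 RNAi against mock, and with unmatched random lists 15 did in drsh-1 RNAi against mock; the cause was not tested. The yolk genes of the direct comparison turned from a median of 1.13 to a mean of -0.54, since 2 of the 5 genes were far lower. Unknown depth leaves the error of genes near 2 FPKM open. No paired analysis was possible because each group had 1 library.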

Other observations

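The search of gene families, the tests of the mock library by its slope and of low-FPKM noise, the value set against microRNA repression, the matching on 3' UTR length and the separate embryonic list were chosen after the results they concern were seen. Gene families sharing a name were placed among random lists. Of 36 families with at least 10 listed genes and few members on the fixed lists, 6 stood apart in dcr-1 RNAi against mock and 5 in drsh-1 RNAi against mock, where 1.8 were expected by chance in each. Vacuolar ATPase subunits (vha, 19 genes) were above mock in both, with a median log2 ratio of 0.49 (99.9th percentile) and 15 genes above 0 in dcr-1 RNAi, and a median of 0.17 (99.8th percentile) and 17 genes above 0 in drsh-1 RNAi. vha-5 had 1.99 and 0.73 in the dcr-1 and drsh-1 libraries and vha-8 had 0.49 and 0.40, whereas vha-12 had -2.47 and -3.60. Galectins (lec, 10 genes) had a median of 0.42 in drsh-1 RNAi (100th percentile), with lec-6 at 479 FPKM in mock and 894 FPKM and 9 genes above mock. Skp1-related genes (skr, 17 genes) had a median of 0.27 there (100th percentile), with skr-10 (1.83) and skr-9 (1.81) the highest and skr-21 (-1.41) the lowest.

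FMRFamide-like neuropeptide genes (flp, 25 genes) had a median of -0.21 in drsh-1 RNAi (0.56th percentile), 18 of them below mock and 0 at least 2-fold apart, flp-21 (-0.64) and flp-4 (-0.62) being the lowest. The nspc family (13 near-identical genes) had a median of -0.19 (0.06th percentile). In dcr-1 RNAi, homeobox genes of the ceh family (15 genes) had a median of -0.59 (0.14th percentile), with 13 below mock, such as ceh-16 (-1.56) and ceh-43 (-1.52), and still stood apart when random lists were matched on 3' UTR length (0.12th percentile). Both ceh-16 (-2.25) and ceh-43 (-1.47) were also low in drsh-1 RNAi against mock, where the family did not stand apart (29.4th percentile). In dcr-1 RNAi, the alh family of aldehyde dehydrogenases had a median of -0.42 (1.67th percentile, 1.09th with matching on 3' UTR length). The rab (-0.25), ubc (-0.16) and ttr (0.27) families did not stand apart with that matching, at the 4.51st, 6.50th and 81.9th percentiles.

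The ratios of both RNAi libraries to mock were correlated across genes. The share of genes with the same sign was 62.7%, and 65.0% to 67.7% for simulated unchanged libraries. This is no like comparison, since the simulations gave the dcr-1 ratio a smaller spread (variance 0.169 simulated and 0.537 observed), so nothing is drawn from it. If the mock library alone departed from the other 2, the slope of the dcr-1 ratio on the drsh-1 ratio across genes would lie between 0 and 1. It was 0.869 (bootstrap 95% interval over genes 0.814 to 0.923), but the simulated unchanged libraries also gave a slope in that range (mean 0.502, 0.470 to 0.543), so the slope decides nothing, and such a mock library and shared effects of RNAi cannot be told apart with 1 mock library. For the collagens the mock library does not account for the difference between dcr-1 RNAi and drsh-1 RNAi, whose ratios use no mock value and whose median was at the 100th percentile. Whether it accounts for the smaller excess of drsh-1 RNAi over mock (median 0.55) cannot be told from that comparison. Open explanations for the collagens include a difference in age at harvest and an effect of dcr-1 RNAi, neither of which was tested.

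In drsh-1 RNAi 6 of 15 early zygotic genes were at least 2-fold higher than in mock (list median at the 97.51st percentile, 95.7th at the lowest) and some genes picked from the lowest, such as dpy-14, ceh-5 and tab-1, lower, while collagens as a list were higher and the ceh family was not apart (median -0.05, 29.4th percentile). Whether noise of genes with low FPKM is the whole cause could not be decided. The 11 early zygotic genes with a mean of at least 5 FPKM had a median of 1.17 (100th percentile of random lists of the same FPKM). That minimum used the mean of both libraries. vet-6, tbx-38 and pes-10, at 4.60, 2.38 and 2.96 FPKM in mock, passed it only through their level in drsh-1 RNAi. The mean of all 15 (100th percentile) restates the pattern, and the median of all 15 was not apart with a pseudocount of 0.1 or 5 FPKM. A candidate explanation is embryos of other ages in both libraries. The separate list of embryonic epidermis, junction and morphogenesis genes was at the 0.11th percentile in drsh-1 RNAi against mock (0.15th when also matched on 3' UTR length). It was chosen after the lowest genes of that comparison were seen, so its low place there is no independent test. In dcr-1 RNAi against mock, where early zygotic genes were not apart, the list was also low, at the 0.27th percentile (5.08th with that matching). In the direct comparison, where early zygotic genes were lower in dcr-1 RNAi, the list was not apart (6.13th percentile, 44.9th with that matching). Of its 70 names 40 were listed above 2 FPKM in mock, 2 of them on a fixed list too, and its most abundant were ceh-43 (127.6 FPKM in mock, log2 ratio -1.47), erm-1 (73.8 FPKM, 0.33) and hmp-2 (72.6 FPKM, -0.11), of which adult tissues may express any. The labels call the animals sterile, and whether embryos were present, and a direct effect of drsh-1 RNAi on these genes, stay open.

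Genes with longer annotated 3' UTRs were lower in dcr-1 RNAi, with a rank correlation of log2 ratio and 3' UTR length of -0.29 against mock (bootstrap 95% interval over genes -0.31 to -0.27), -0.29 against drsh-1 RNAi and -0.05 for drsh-1 RNAi against mock. In the quintile of genes with the longest 3' UTRs (354 to 5363 nt), the median was -0.25 and 15.1% were at least 2-fold lower, against 0.19 and 4.90% in the quintile with the shortest. A loss of long transcripts in general is argued against by a partial correlation of 0.0369 with the rest of the transcript, and transcripts dropped from genes with several transcripts by a correlation of -0.27 among genes with 1 annotated transcript. Loss of microRNA repression would raise genes with long 3' UTRs, so the pattern's own sign (-0.29), which is no separate test, is the reverse of what it needs. A difference in coverage of 3' ends or RNA quality between the libraries, which needs reads, and an effect of dcr-1 RNAi stay open, with 1 library each.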
